A study of Mus musculus with 8 samples.

How the data were processed

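RNA of 8 cultures of mouse embryonic fibroblasts was measured, Atm+/+ and Atm-/- at 0, 4, 8 and 24 h after neocarzinostatin (NCS), with 1 array per genotype and time point. Per the labels, the cells were kept in medium with 15% fetal calf serum, total RNA was taken with Trizol, ribosomal RNA was removed, and random priming along the whole transcript gave a Cy3-labelled target for one-colour Agilent arrays. Per the file headers, Feature Extraction 10.5.1.1 read the scans, and each spot holds a processed signal, an intensity from which background was subtracted and spatial trends removed within the array, and which was not normalized between arrays. The files also hold the median pixel intensity of each spot and of its local background, per the file headers, but no mean pixel signal. The arrays follow the mouse assembly mm9. The other deposited tables hold 7633 noncoding probes only. In one of them the authors give log2 values that a header line calls ratios to 0 h, but each column equals log2 of the processed signal minus 1 constant per array, from 7.21 to 7.47. The other deposited table repeats the processed intensity, with log2 differences of at most 0.000962. All 7633 deposited probes were well above background on at least 1 array, and the 7085 noncoding probes of the same design sets that the authors left out were so on none.

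Control spots were left out, replicate spots of a probe were averaged on the log2 scale, and levels were set relative to the 75th percentile of all 37246 measured probes of the array. A value was then left out where Feature Extraction had marked every spot of the probe as an outlier. Marked spots of other probes stayed in their mean. The marked spots numbered 54, 44, 195 and 1545 on the Atm+/+ arrays at 0, 4, 8 and 24 h. On the Atm-/- arrays they numbered 128, 96, 145 and 203. In a first version these spots were removed before the percentile was taken, which raised the Atm+/+ 24 h array by 0.37 log2 and the others by 0.00 to 0.05. This was changed after the counts of the first version had been seen, and the change raised the counts of the genotype and 24 h comparisons. The first version put the median of all probes at 0.12 in place of -0.07 at 24 h and at -0.11 in place of 0.01 in the difference of response. Of 37246 probes, 23296 were well above background on at least 2 arrays and were kept, 6742 of them noncoding. A probe was taken as noncoding where the deposited tables hold it and its RefSeq transcript, if any, is not a coding one. Gene symbols came from the RefSeq transcript of a probe. Of the kept probes 16398 carried 1 gene symbol, for 13953 distinct symbols, and 161 noncoding probes were among them.

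limma 3.58.1 in R 4.3.3 was used for all tests of probes and lists, two-sided, with moderated t-tests for probes and Benjamini-Hochberg adjustment over the kept probes with a value. A probe was called at an adjusted p under 0.05. Chance alone would put 1146 to 1164 of the kept probes at an unadjusted p under 0.05, depending on the comparison. A Fisher exact test, exact binomial intervals and Dixon ratios were used for the few other comparisons. The genotype comparison and the responses to NCS at 4, 8 and 24 h and over all of them came from a model with time point and genotype as terms. The responses within a genotype came from a model with 4 groups, genotype by treatment, and the difference of response from a model with time point, genotype and genotype by treatment, which leaves 2 residual degrees of freedom. Probes dim on every array of a side were given as bounds against the lowest spot well above background on the array. An earlier version took the lowest probe mean, which was too low where dim spots entered the mean, so the bounds were lowered after they had been seen. The responses at 4, 8 and 24 h share the untreated arrays, so their calls were not compared with one another. The labels give no replicate numbers. Ratios of single arrays were counted at 2-fold among probes well above background on both arrays, without a test.

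Lists of 21 gene groups, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The lists are p53 targets, long noncoding RNAs linked to DNA damage and p53, G2/M, S phase, DNA repair and checkpoint, NF-kB and inflammatory cytokines, interferon-stimulated, immediate-early and stress, oxidative stress (Nrf2), core histones, extracellular matrix, Hox, imprinted, X inactivation and Y-linked, neighbours of Atm on chromosome 9, and markers of epithelium, endothelium, blood and macrophages, muscle, nerve, and cartilage, bone and fat. Lists with at least 5 genes measured on every array were tested with camera at the preset correlation of 0.01, again with the correlation estimated, and with fry, using the probe with the highest mean per gene, and p was adjusted over lists within a comparison. Single-array list medians were ranked among 10000 random lists of the same size matched in 20 bins of mean level. Named genes are Atm, the 10 largest called rises and falls that moved the same way in every pair or genotype, 5 noncoding ones each way, up to 5 with the smallest p where fewer than 5 passed, the 5 largest single-array ratios each way, up to 4 called members of each list or otherwise 3 with the highest mean, and the controls Cdkn1a, Mdm2, Ccng1, Trp53inp1, Trp53cor1, Pvt1, Neat1, Malat1, Gas5, H19, Meg3 and Xist. No probe carried the symbol Trp53cor1, Gas5 or H19.

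The steps were tested on simulated data of 21560 genes with known changes of 2-fold, 4-fold and 8-fold. The genotype comparison recovered 64.2%, 86.6% and 98.5% of them, the response over all time points 53.7%, 82.1% and 93.9%, the responses at 4 h 26.9%, 82.1% and 87.9%, at 8 h 26.9%, 82.1% and 84.8% and at 24 h 37.3%, 83.6% and 90.9%. The response within Atm+/+ recovered 25.4%, 79.1% and 87.9%, within Atm-/- 32.8%, 76.1% and 93.9%, and the difference of response 0%, 0% and 0%. A simulated list shifted by 0.5 log2 was found by camera with the preset correlation in all comparisons, and with the estimated one in all but the difference of response (adjusted p = 0.621), and 0 of 19 random lists were called. The simulated genes varied independently, so the simulated lists do not check the preset correlation. In the genotype comparison the estimated correlation was 0.35 for S phase and 0.31 for NF-kB genes. The number of arrays, 8 in all, limits the precision of every estimate.

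Alternatives tried were quantile normalization, the authors' values, probes well above background on all 8 arrays or without such a filter, eBayes with trend and robust set, leaving out each array and each time point, time point left out of the model or replaced by treatment, only the 4 arrays of a genotype, a 3-fold threshold, detection on at least 1 of both arrays, and the mean of all probes of a gene. Scaling to the array median, normexp with an offset of 50 on median spot intensities, outlier spots kept, and the percentile taken after removal of outlier spots were added after seeing the data. Slide and scan could not be used as a block for genotype, because no slide holds both genotypes. Calculations outside R used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9. Chromosomes came from the RefSeq annotation of the gene symbol, and no positions within a chromosome were used.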

Results

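RNA from mouse embryonic fibroblasts (MEFs, connective tissue cells grown from embryos) was measured on arrays carrying probes for long noncoding and coding transcripts. The cells came from littermates with Atm (Atm+/+) or described as lacking it (Atm-/-). Atm encodes the kinase that reports DNA double-strand breaks to p53 and to the cell cycle checkpoints. Cells were untreated (0 h) or collected 4, 8 and 24 h after neocarzinostatin (NCS), a drug that breaks DNA much as ionizing radiation does. The question behind the series is how long noncoding RNAs are controlled when DNA is damaged. There are 8 arrays, 1 for each genotype at each time point, and the labels do not say how many embryos or cell lines they stand for. The limma p-values of probes below therefore measure the spread between arrays of different time points and genotypes, which may be largely technical. A camera p-value sets a list against the other genes. With the preset correlation of 0.01, used unless an estimated one is named, it rests mainly on the spread over genes. The Fisher exact p takes probes as units. No p-value below measures the spread between embryos or cell lines.

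All 4 Atm+/+ arrays lay on one slide and all 4 Atm-/- arrays on another, so a difference between genotypes cannot be told from a difference between slides. Time points followed array positions 1 to 4 on both slides, and there were 0 untreated arrays at 4, 8 or 24 h, so a response to NCS cannot be told from time in culture or array position. Between 57.3% and 61.4% of the spots on an array were well above background. Pearson r across 21560 probes was 0.987 to 0.993 within Atm+/+, 0.985 to 0.994 within Atm-/- and 0.974 to 0.985 between genotypes, and probes are not independent replicates. Levels are log2 intensity relative to the 75th percentile of the array, and errors are standard errors (SE).

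Atm itself read -2.07, -2.18, -1.95 and -2.43 on the Atm+/+ arrays at 0, 4, 8 and 24 h, and -3.19, -3.57, -3.67 and -3.15 on the Atm-/- arrays. The difference was -1.24 ± 0.18 (4 arrays against 4, limma adjusted p = 0.0137), and Atm was lower in Atm-/- in 4 of 4 pairs of arrays. Without the 0 h arrays it was -1.28 (adjusted p = 0.0617) and without the 4 h arrays -1.19 (adjusted p = 0.0667), so the call was lost in both cases. The probe was well above background in both genotypes, so RNA that it detects was still present in Atm-/-. The labels do not give the deleted part of the gene, a probe outside that part checks nothing, and the value does not show that Atm was absent.

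Transcripts of the Y chromosome were among those that differed most between the genotypes, a comparison that asks what loss of Atm changes at every time point (Atm-/- minus Atm+/+, 4 arrays against 4). Of the Y-linked genes, Ddx3y was lower in Atm-/- by a log2 difference of -11.57 ± 0.08 (bound -9.45), and Eif2s3y and Uty were at least 517-fold and 97.9-fold lower. Kdm5d had a log2 difference of -7.80 ± 0.11 (bound -5.75), and the noncoding transcript uc009uzk was at least 708-fold lower. Xist, the noncoding RNA that silences one X chromosome, was higher by 4.99 ± 0.06 (bound 2.67) on one probe and by 4.19 ± 0.58 on the other (raised, a term explained below, 5.67-fold). Y-linked transcripts were thus seen in Atm+/+ and Xist in Atm-/-, the pattern of male and female cells. The labels do not give embryo sex, and if the littermates differed in it, no genotype value here can be told from a difference of sex any more than from one of slide. For a bound, each reading on the side that was nowhere well above background is raised to at least the lowest spot well above background on its array, and the means are compared. Where some arrays of a side were dim, the same step gives the value called raised. The list of X inactivation and Y-linked genes had 5 measured members, 1 higher and 4 lower, with the same counts adjusted over the list alone, and too few measured on every array for camera.

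Interferon-stimulated genes, which answer viral nucleic acid and interferon, were lower in Atm-/-: 26 of 32 measured passed and all 32 did when adjusted over the list alone. Their median was -1.21 (limma camera adjusted p = 1.86e-20, adjusted p = 0.141 with an estimated correlation). The antiviral genes Oasl2 (-2.99 ± 0.07, adjusted p = 0.000336) and Oas1a (-2.50 ± 0.30, bound -1.16), the nucleic acid sensor gene Zbp1 (-1.99 ± 0.07) and the RNA-binding Ifit1 (-1.99 ± 0.14) were lower. Markers of blood cells and macrophages were lower beside them, 11 of 14 and 12 adjusted over the list alone (median -1.13, camera adjusted p = 1.21e-08, adjusted p = 0.141 with an estimated correlation). They included the lysozymes Lyz1 (-1.45 ± 0.09) and Lyz2 (-1.33 ± 0.09), the integrin Itgam (-1.44 ± 0.16) and the complement gene C1qa (-1.39 ± 0.12). Of 34 NF-kB and inflammatory cytokine genes 11 were lower and 1 higher, and 14 and 2 adjusted over the list alone (median -0.43, camera adjusted p = 7.21e-05, adjusted p = 0.423 with an estimated correlation). The chemokine genes Cxcl5 (-0.90 ± 0.10), Ccl7 (-0.90 ± 0.19) and Ccl2 (-0.87 ± 0.16) and the matrix protease gene Mmp10 (-0.92 ± 0.10) were among the lower ones.

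Markers of bone, cartilage and fat were higher in Atm-/-, 6 of 12 and 7 adjusted over the list alone (median 1.05, camera adjusted p = 9.47e-05, adjusted p = 0.175 with an estimated correlation). Alkaline phosphatase Alpl was higher by 3.15 ± 0.49 (raised 3.10) and the bone transcription factor Sp7 by 2.23 ± 0.38 (raised 1.78), and the fat cell genes Pparg (1.74 ± 0.11) and Fabp4 (1.09 ± 0.13) were higher too. Epithelial markers were higher for 8 of 12 genes, and for 9 higher and 1 lower adjusted over the list alone (median 0.78, camera adjusted p = 0.000176, adjusted p = 0.175 with an estimated correlation). The tight junction genes Cldn4 (1.22 ± 0.13) and Cldn7 (1.21, raised 0.90) and the keratin Krt14 (1.11 ± 0.07) were in front. Endothelial markers were higher for 4 of 12, and 5 higher and 1 lower adjusted over the list alone (median 0.27, camera adjusted p = 0.0170, adjusted p = 0.198 with an estimated correlation). The VEGF receptor Kdr (1.76 ± 0.09) led them. Core histone genes were higher for 19 of 45 and lower for 2, and 28 and 2 adjusted over the list alone (median 0.46, camera adjusted p = 1.21e-08, adjusted p = 0.175 with an estimated correlation). H2ac22 (1.00 ± 0.15), H2bc22 (0.88 ± 0.13) and H4c8 (0.79) were higher and H2ac11 (-0.86) lower. Nrf2 targets, which detoxify oxidants, were higher for 5 of 25 and lower for 2, and 8 and 2 adjusted over the list alone (median 0.23, camera adjusted p = 0.00442, adjusted p = 0.175 with an estimated correlation). The glutathione transferases Gsta2 (2.31 ± 0.21, raised 1.96) and Gsta1 (2.06 ± 0.09) and the quinone reductase Nqo1 (0.78) were higher and the cystine carrier Slc7a11 (-0.72) lower.

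G2/M genes were lower for 5 of 39 and for 6 adjusted over the list alone (median -0.14, camera adjusted p = 0.00233, adjusted p = 0.484 with an estimated correlation). The mitotic genes Plk1 (-0.47), Top2a (-0.42), Bub1b (-0.40) and Sgo1 (-0.39) were among them. DNA repair and checkpoint genes were lower for 2 of 38, Atm and the checkpoint kinase Chek1 (-0.50 ± 0.10), and for 1 adjusted over the list alone (median -0.15, camera adjusted p = 0.00404, adjusted p = 0.452 with an estimated correlation). Extracellular matrix genes did not pass camera (adjusted p = 0.105, adjusted p = 0.287 with an estimated correlation, median -0.18), yet 9 of 35 were lower and 3 higher, and 10 and 7 adjusted over the list alone. Periostin Postn (-1.21 ± 0.12), Pdgfra (-1.16 ± 0.11), elastin Eln (-0.89) and the collagen Col1a2 (-0.81) were lower. With fry extracellular matrix genes were lower as a list (adjusted p = 0.00485). G2/M and DNA repair genes missed the threshold with fry (adjusted p = 0.0853 each).

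Targets of p53 showed no common direction: 4 of 47 were higher and 3 lower, with the same counts adjusted over the list alone (median 0.03, camera adjusted p = 0.509, adjusted p = 0.786 with an estimated correlation). The median of these genes became -0.04 when outlier spots were removed before scaling. The stress cytokine Gdf15 (1.10 ± 0.19) and Plk2 (0.71) were higher, and Casp1 and the peptide transporter Tap1 (-0.78) lower. Cdkn1a, which encodes the p21 inhibitor of the cell cycle, read 0.54 ± 0.20 and 0.48 on its probes (adjusted p = 0.132 for the former) and Mdm2 -0.30 ± 0.17 (adjusted p = 0.273). The named long noncoding RNAs had 2 of 16 higher, Meg3 (0.93 ± 0.16) and Rmrp (0.48 ± 0.09), and the same 2 adjusted over the list alone (median 0.06, camera adjusted p = 0.585, adjusted p = 0.786 with an estimated correlation). The median of these RNAs was -0.01 when outlier spots were removed before scaling. Malat1 read -0.10 and Neat1 0.09.

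The remaining lists also missed the camera threshold. S phase and replication genes had 1 of 37 lower, the helicase gene Mcm6 (-0.85 ± 0.14), and 0 adjusted over the list alone (median -0.09, camera adjusted p = 0.0857, adjusted p = 0.786 with an estimated correlation). Immediate-early and stress genes had 4 of 35 higher and 4 lower, and 7 and 4 adjusted over the list alone (median 0.10, camera adjusted p = 0.402, adjusted p = 0.786 with an estimated correlation). Maff (0.86) and the phosphatase Dusp1 (0.72) were higher and Trib3 (-0.81) and Egr2 (-0.48) lower. Imprinted genes had 5 of 25 higher, and 6 higher and 1 lower adjusted over the list alone (median 0.25, camera adjusted p = 0.0690, adjusted p = 0.269 with an estimated correlation). Peg10 (0.79), Dlk1 (0.76) and Zim1 (0.58) were higher beside Meg3. With fry imprinted genes were higher as a list (adjusted p = 0.00289). Hox genes had 3 of 34 higher, Hoxb9 (0.69), Hoxb4 (0.36) and Hoxa11os (0.31), and 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.509, adjusted p = 0.786 with an estimated correlation). The median of the Hox genes was -0.02 when outlier spots were removed before scaling. Neighbours of Atm on chromosome 9 had 1 of 17 higher, Elmod1 (0.83 ± 0.14), and 2 lower, Atm and Arhgap20 (-0.48 ± 0.09), with the same counts adjusted over the list alone (camera adjusted p = 0.955, adjusted p = 0.955 with an estimated correlation). Their median was 0.03 and the camera direction down, and the median was -0.05 when outlier spots were removed before scaling. Muscle markers had 2 of 12 higher, Tnnt2 (0.72) and desmin Des (0.67), and 1 lower, Myf5 (-0.82), and 3 and 2 adjusted over the list alone (median 0.09, camera adjusted p = 0.596, adjusted p = 0.786 with an estimated correlation). Neural markers had 1 of 15 higher, Sox10 (0.39), and 2 lower, Gfap (-0.90) and Snap25 (-0.62), and 3 and 5 adjusted over the list alone (median -0.34, camera adjusted p = 0.465, adjusted p = 0.692 with an estimated correlation).

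Single transcripts outside the lists differed by more than most list members. BC040080 was higher by 5.17 ± 0.15. Musk, the muscle kinase of the neuromuscular junction, was at least 8.95-fold higher on the probe named here, and all 5 of its probes passed. The noncoding uc007zio was higher by 2.74 ± 0.13, neuritin Nrn1 by 2.64 ± 0.23 and Trim58 by 2.63 ± 0.12 (raised 5.66-fold). Zfp74 was at least 45.9-fold lower, and AK007219 (-4.31 ± 0.61), the NF-Y subunit gene Nfyb (-3.98 ± 0.10) and AK012915 (-3.65 ± 0.14, at least 2.78-fold) were lower. With limma 3418 of 23270 probes passed at an adjusted p of 0.05 (two-sided), 1698 higher and 1720 lower in Atm-/-, and 918 of them were noncoding (472 higher, 446 lower).

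Leaving out the 0, 4 or 8 h arrays, or either one of the pair, gave 1140, 1090 or 1323 calls, and leaving out the 24 h arrays gave 4220. In the first version of the analysis, in which outlier spots were removed before scaling, 2250 probes passed with 39.9% higher in place of 49.7%, and a model-based background correction gave 39.1% higher.

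**Figure D1:**
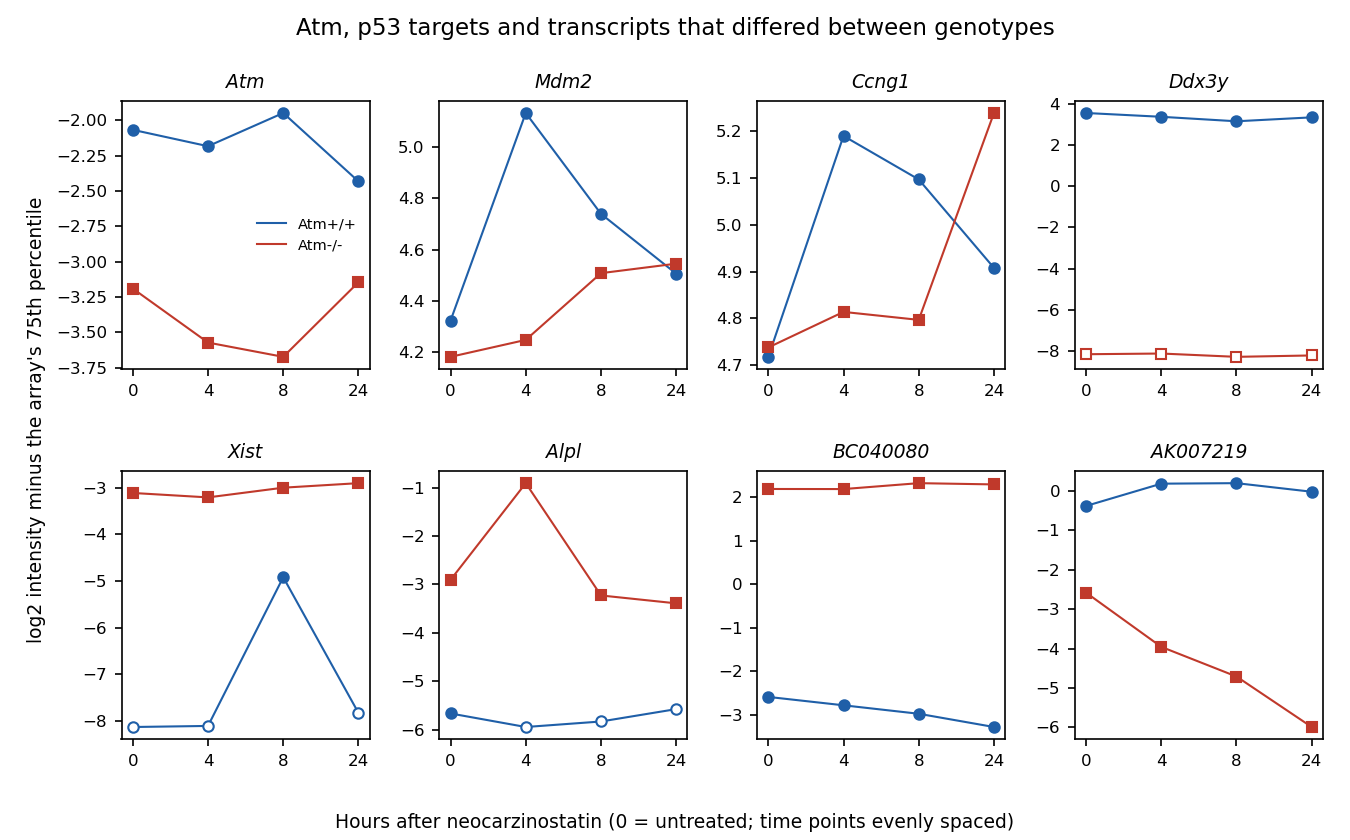
Log2 intensity relative to the 75th percentile of the array (vertical) against hours after NCS with time points evenly spaced (horizontal), 1 array per point. The panels show Atm, the p53 targets Mdm2 and Ccng1, and Ddx3y, Xist, Alpl, BC040080 and AK007219, which differed between genotypes. Lines join the arrays of a genotype, and open markers stand for spots not well above background. BC040080 ran from -2.59 to -3.29 in Atm+/+ and from 2.19 to 2.33 in Atm-/-.

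Some cytokine genes rose after NCS (10 of 34 on the NF-kB list), in a comparison of the 2 untreated arrays with the 6 treated ones that asks which transcripts respond with or without Atm. Il1b rose by 4.97 ± 0.18 (bound 4.52) and Acod1, whose enzyme makes itaconate in activated macrophages, by 4.34 ± 0.16 (limma adjusted p = 0.00405). Ccl3 rose by 3.81 ± 0.14, Il1a by 3.68 ± 0.12, the chemokine Ccl20 by 3.64 ± 0.29, the acute-phase gene Saa3 by 3.46 ± 0.23 and Tnf by 3.38 ± 0.25. The cornified envelope genes Sprr2d and Sprr2e rose at least 16.4-fold and 3.55-fold. Among noncoding transcripts AK036493 rose by 4.31 ± 0.19, uc007pps by 2.24 ± 0.11 (raised 1.71), AK030791 by 1.96 ± 0.15, AK044397 by 1.95 ± 0.09 and AK169930 by 1.81 ± 0.10. BC037679 (-1.27 ± 0.12, bound -0.48) and AK142897 (-1.12 ± 0.09, bound -0.49) fell. On the untreated Atm-/- array Acod1, AK036493 and Il1a were not well above background, but their readings lay above the lowest spot that was, so the raised values of these genes equal the values given here and at 4 and 8 h.

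NF-kB and inflammatory cytokine genes had 10 of 34 higher, and 30 higher and 1 lower adjusted over the list alone (median 1.30, camera adjusted p = 2.70e-29, adjusted p = 0.245 with an estimated correlation). Interferon-stimulated genes had 0 calls and 15 higher adjusted over the list alone (median 0.50, camera adjusted p = 7.41e-18, adjusted p = 0.245 with an estimated correlation). Blood and macrophage markers had 0 calls and 5 higher adjusted over the list alone (median 0.27, camera adjusted p = 0.00376, adjusted p = 0.361 with an estimated correlation). Genes of S phase (median -0.42, camera adjusted p = 9.04e-13, adjusted p = 0.385 with an estimated correlation) and of G2/M (median -0.36, camera adjusted p = 5.64e-12, adjusted p = 0.361 with an estimated correlation) each had 0 calls and 17 lower adjusted over the list alone. DNA repair genes (median -0.19, camera adjusted p = 0.00166, adjusted p = 0.532 with an estimated correlation) had 0 calls and 0 adjusted over the list alone. Epithelial markers (median -0.25, camera adjusted p = 0.0302, adjusted p = 0.432 with an estimated correlation) had 0 calls and 1 lower adjusted over the list alone. Targets of p53 had 0 calls and 1 higher adjusted over the list alone (median 0.15, camera adjusted p = 0.000132, adjusted p = 0.432 with an estimated correlation). Mdm2 (0.36 ± 0.19, adjusted p = 0.464), which restrains p53, Trp53inp1 (0.40 ± 0.18, adjusted p = 0.458) and Ccng1 (0.28 ± 0.16, adjusted p = 0.490) did not pass, and neither did Malat1 (-0.24, adjusted p = 0.368) or Meg3 (-0.40, adjusted p = 0.416). The remaining 12 lists had camera adjusted p from 0.270 to 0.973.

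With limma 48 of 23133 probes passed, 46 higher and 2 lower, and 9 were noncoding (7 higher, 2 lower). Without the 0 h array of Atm+/+ or of Atm-/- limma called 0 (1272 and 1715 at unadjusted p under 0.05). Without the 4, 8 or 24 h array it called 23, 14 and 41 for Atm+/+ and 21, 15 and 22 for Atm-/-.

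**Figure D2:**
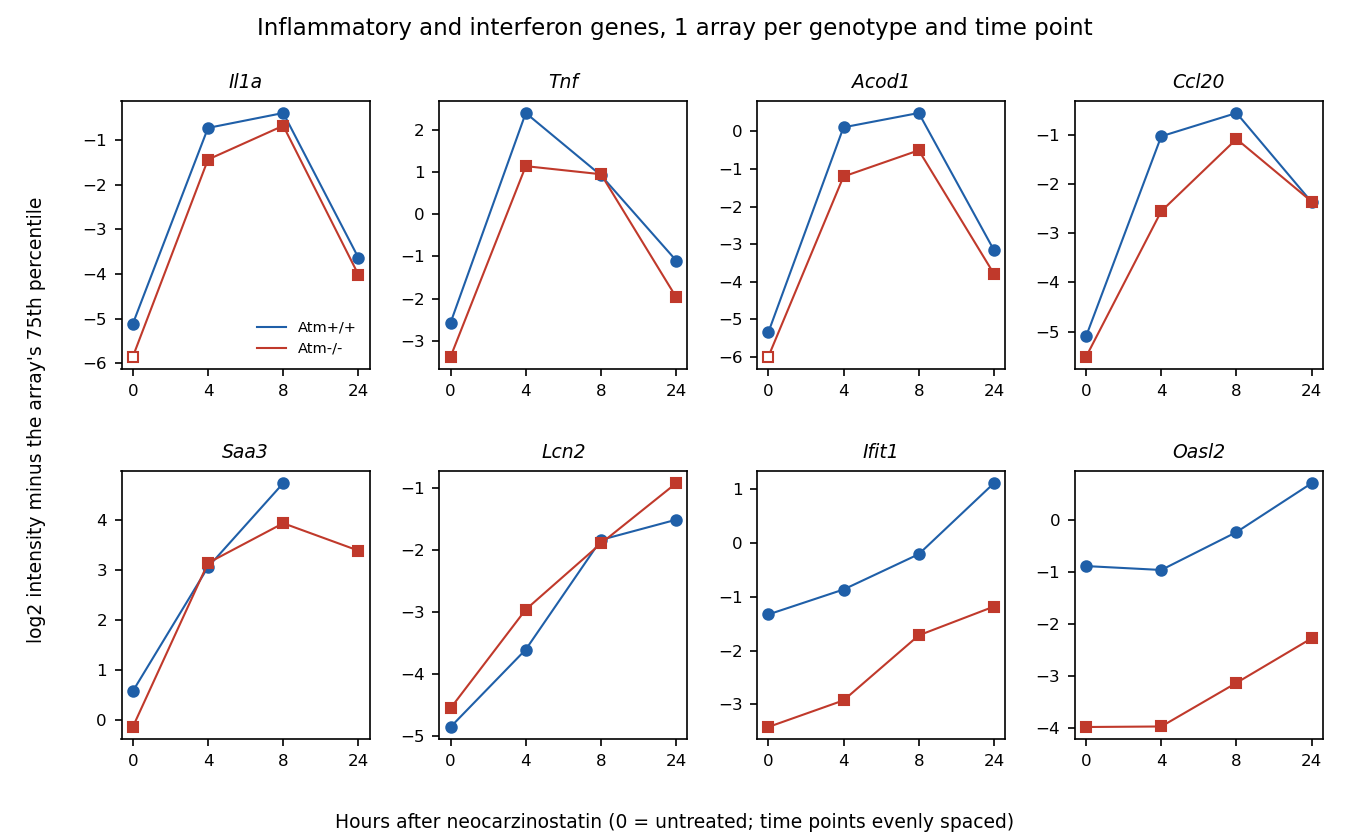
Log2 intensity relative to the 75th percentile of the array (vertical) against hours after NCS with time points evenly spaced (horizontal), 1 array per point. The panels show the inflammatory genes Il1a, Tnf, Acod1, Ccl20, Saa3 and Lcn2 and the interferon-stimulated genes Ifit1 and Oasl2. Lines join the arrays of a genotype, and open markers stand for spots not well above background. Acod1 read -5.36, 0.11, 0.49 and -3.16 at 0, 4, 8 and 24 h in Atm+/+.

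At 4 h, the earliest look at the response, 5 of 34 NF-kB genes had already risen (2 arrays against 2). Il1b rose at least 59.5-fold, Acod1 by 5.14 ± 0.20 (limma adjusted p = 0.00482), Tnf by 4.76 ± 0.31 and Il1a by 4.42 ± 0.15, the chemokine Ccl4 by 4.28 ± 0.34 and the activation marker Cd69 by 3.84 ± 0.20. Cxcl2 and the growth factor Csf2 rose at least 6.03-fold and 3.88-fold. AK036493 rose by 4.93 ± 0.24, AK030791 by 2.26, uc007pps by 2.18 (raised 1.65), AK044397 by 1.87 and AK080203 by 1.41. Arhgap25, a GTPase regulator of leukocytes, fell (-1.60 ± 0.12) and passed on both of its probes. NF-kB genes had 5 higher and 23 adjusted over the list alone (median 1.15, camera adjusted p = 1.90e-44, adjusted p = 0.277 with an estimated correlation). Targets of p53 had 0 calls and 0 adjusted over the list alone (median 0.19, camera adjusted p = 4.50e-08, adjusted p = 0.489 with an estimated correlation), as had extracellular matrix genes (median -0.12, camera adjusted p = 0.00961, adjusted p = 0.359 with an estimated correlation) and interferon-stimulated genes (median 0.07, camera adjusted p = 0.0252, adjusted p = 0.766 with an estimated correlation). Blood and macrophage markers had a median of 0.03 (camera adjusted p = 0.224). With limma 24 of 23268 probes passed, 22 higher and 2 lower. At unadjusted p under 0.05 there were 940, fewer than the 1163 expected by chance. Without the 0 h or 4 h array of Atm+/+ (766 and 686 at unadjusted p under 0.05) or of Atm-/- (782 and 819) limma called 0. It called 10 without the 8 h array of Atm+/+ or Atm-/-, and 8 without the 24 h array of Atm+/+ or Atm-/-.

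At 8 h 12 of 34 NF-kB genes stood above their untreated level (2 arrays against 2). Sprr2d rose at least 47.8-fold, and Acod1 by 5.68 ± 0.20 (limma adjusted p = 0.00345). AK036493 rose by 5.68 ± 0.24, Il1a by 4.96 ± 0.15, Ccl20 by 4.48 ± 0.36, Saa3 by 4.11 ± 0.27, the chemokine Cxcl3 by 4.00 ± 0.29 (raised 4.00) and Tnf by 3.92 ± 0.31. AK044397 (2.76), uc007pps (2.74, raised 2.20), AK030791 (2.41) and AK080203 (2.38) rose, and AK015453 (-1.42 ± 0.11, bound -0.41), AK142897 (-1.27 ± 0.11, bound -0.49), Arhgap15 (-1.05 ± 0.10, raised -0.81) and Palmd (-1.01 ± 0.09) fell. NF-kB genes had 12 higher and 32 adjusted over the list alone (median 1.70, camera adjusted p = 3.10e-34, adjusted p = 0.304 with an estimated correlation). Interferon-stimulated genes (median 0.46, camera adjusted p = 8.47e-12, adjusted p = 0.304 with an estimated correlation) had 0 calls and 13 higher adjusted over the list alone, and blood and macrophage markers (median 0.33, camera adjusted p = 0.0378, adjusted p = 0.637 with an estimated correlation) had 0 calls and 3. S phase genes (median -0.34, camera adjusted p = 1.79e-07), Hox genes (median -0.21, camera adjusted p = 0.00898) and p53 targets (median 0.12, camera adjusted p = 0.00340) had adjusted p = 0.637 with an estimated correlation each. With limma 60 of 23261 probes passed, 56 higher and 4 lower. Without the 0, 4, 8 or 24 h array of Atm+/+ limma called 1, 25, 8 and 85, and of Atm-/- 0, 25, 0 and 85 (1709 and 2391 at unadjusted p under 0.05 beside the 0 counts).

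At 24 h, which asks what follows the first wave, 8 of 32 interferon-stimulated genes were higher and 19 of 39 G2/M and 9 of 37 S phase genes lower (2 arrays against 2). The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.308, 0.336 and 0.336). The iron-binding Lcn2 rose by 3.49 ± 0.20 (limma adjusted p = 0.0353), Saa3 by 3.40 ± 0.36, haptoglobin Hp by 3.20 ± 0.36, complement C3 by 2.49 ± 0.24, the macrophage receptor Marco by 2.72 ± 0.11 and the calcium-binding Calb2 by 4.00 ± 0.14 (raised 3.59). Ifit3 (2.63 ± 0.26), Ifit1 (2.34 ± 0.20), Oasl2 (1.65 ± 0.10), Zbp1 (1.59 ± 0.11) and Lyz2 (1.30 ± 0.12) rose. The mitotic genes Kif2c (-1.31 ± 0.12), Espl1 (-1.18 ± 0.11) and Hmmr (-1.17 ± 0.15) and the kinase gene Cdk1 (-1.32 ± 0.13, bound -0.82) fell. So did the replication genes Tk1 (-1.22 ± 0.15), Cdt1 (-1.10 ± 0.14) and Prim1 (-1.02 ± 0.12) and the repair genes Palb2 (-0.88) and Fanca (-0.81). The metallothioneins Mt2 (-1.86 ± 0.19) and Mt1 (-1.54 ± 0.13) fell too, as did Kdr (-1.27 ± 0.12), Dock3 (-1.69 ± 0.14, raised -1.41) and the noncoding AK082312 (-2.33 ± 0.31, raised -1.52). The noncoding uc008wdi rose at least 2.20-fold.

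G2/M genes had 19 of 39 lower and 33 adjusted over the list alone (median -0.85, camera adjusted p = 1.22e-17, adjusted p = 0.336 with an estimated correlation), and S phase genes 9 of 37 and 33 (median -0.83, camera adjusted p = 2.44e-14, adjusted p = 0.336 with an estimated correlation). DNA repair genes had 3 of 37 lower and 17 adjusted over the list alone (median -0.38, camera adjusted p = 2.71e-05, adjusted p = 0.349 with an estimated correlation). Interferon-stimulated genes had 8 higher and 26 adjusted over the list alone (median 0.95, camera adjusted p = 5.92e-19, adjusted p = 0.308 with an estimated correlation). NF-kB genes had 9 higher, and 17 higher and 1 lower adjusted over the list alone (median 0.87, camera adjusted p = 2.25e-07, adjusted p = 0.349 with an estimated correlation). Blood and macrophage markers had 1 higher and 6 adjusted over the list alone (median 0.55, camera adjusted p = 0.00587, adjusted p = 0.336 with an estimated correlation). Epithelial markers had Krt8 (-0.94) lower and 7 adjusted over the list alone (median -0.55, camera adjusted p = 0.00272, adjusted p = 0.336 with an estimated correlation). Muscle markers had Myod1 (-0.98) lower and 4 adjusted over the list alone (median -0.43, camera adjusted p = 0.0368, adjusted p = 0.483 with an estimated correlation). Immediate-early genes had Fosl1 (-0.84) lower, alone also over the list alone (median -0.27, camera adjusted p = 0.0102, adjusted p = 0.479 with an estimated correlation). Targets of p53 had Casp1 (0.78 ± 0.09) higher, and 2 higher and 2 lower adjusted over the list alone (median 0.14, camera adjusted p = 0.0252, adjusted p = 0.595 with an estimated correlation). Malat1 (-0.51, adjusted p = 0.0881) and Meg3 (-0.73, adjusted p = 0.135) did not pass. All these medians depend on the scale. In the first version, with outlier spots removed before scaling, they were -0.66 for G2/M, -0.64 for S phase, -0.19 for DNA repair, 1.15 for interferon-stimulated, 1.02 for NF-kB, 0.74 for blood and macrophage, -0.36 for epithelial, -0.24 for muscle, -0.07 for immediate-early and 0.32 for p53 target genes. Against its untreated array, the 24 h array of Atm+/+ had a median of -0.25 for immediate-early genes, which became 0.12.

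With limma 511 of 23141 probes passed at 24 h, 218 higher and 293 lower, 111 of them noncoding (34 higher, 77 lower). In the first version, with outlier spots removed before scaling, 33 passed and 93.9% were higher in place of 42.7%, and scaling to the median of each array gave 179 with 69.8% higher. Without the 0, 4, 8 or 24 h array of Atm+/+ (3042, 4550, 5494 and 7979 at unadjusted p under 0.05) or the 0, 4 or 8 h array of Atm-/- (3421, 4550 and 5494) limma called 0, and without the 24 h array of Atm-/- it called 6.

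Within a genotype, 1 untreated array was set against 3 treated ones to ask whether the response needs Atm. With limma 2 of 23263 probes passed in Atm+/+, Olfr533, an odorant receptor gene (at least 10.7-fold lower), and the glycosyltransferase gene B3gnt2 (-2.43 ± 0.18, adjusted p = 0.0436). In Atm-/- 6 of 23186 passed, 1810030O07Rik (2.88 ± 0.16) and Zfp182 (2.11 ± 0.18, other probe 0.11) upward and Chga (-4.79 ± 0.31), Riok3 (-3.84 ± 0.32, raised -3.81), uc007uml and uc009lsv (both -2.21 ± 0.18) downward. These calls rest on the single untreated array of the genotype and cannot be read as responses to NCS. In each genotype fewer probes had unadjusted p under 0.05 than chance would give. B3gnt2 read 3.65 on the untreated Atm+/+ array and 1.14 to 1.41 on the other 7 arrays. On the untreated Atm-/- array 1810030O07Rik read -1.05 against 1.77 to 2.01 elsewhere. Chga read -0.48 against -4.21 to -5.73 and Riok3 -1.84 against -5.35 to -6.18. NF-kB genes had a median of 1.47 in Atm+/+ (camera adjusted p = 3.53e-19, adjusted p = 0.398 with an estimated correlation) and 1.06 in Atm-/- (camera adjusted p = 1.47e-13, adjusted p = 0.666 with an estimated correlation), with 0 calls and 0 adjusted over the list alone in both. Targets of p53 had medians of 0.19 (camera adjusted p = 9.01e-07, adjusted p = 0.331 with an estimated correlation) and 0.12 (camera adjusted p = 0.00596, adjusted p = 0.666 with an estimated correlation). Leaving out the 4, 8 or 24 h array of Atm+/+ changed its limma count to 3, 0 and 0 (502 and 725 at unadjusted p under 0.05 for the counts of 0). The 4, 8 or 24 h array of Atm-/- changed it to 3, 1 and 0 (966). The Atm-/- count became 2 and 0 (710) without the 4 and 24 h arrays of Atm+/+, and 1, 3 and 2 without the 4, 8 and 24 h arrays of Atm-/-.

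The difference between these responses (Atm-/- minus Atm+/+) asks most directly what Atm controls after damage. S phase genes had a median of 0.29 (camera adjusted p = 8.84e-08) and DNA repair genes 0.15 (camera adjusted p = 0.00117). G2/M genes had 0.16 (camera adjusted p = 0.0113), NF-kB genes -0.29 (camera adjusted p = 0.00117) and p53 targets -0.13 (camera adjusted p = 0.0547). Each of these lists had adjusted p = 0.717 with an estimated correlation, and fry gave adjusted p = 0.496 for S phase, 0.543 for DNA repair and 0.762 for the others. Each response rests on 1 untreated array. In the first version, with outlier spots removed before scaling, the medians were 0.16 for S phase, 0.03 for DNA repair, 0.03 for G2/M, -0.42 for NF-kB and -0.25 for p53 targets. limma called 0 of 22928 probes (568 at unadjusted p under 0.05, with 1146 expected by chance). Simulated changes of this kind were recovered at 0% for 2-fold, 4-fold and 8-fold alike, so the 0 calls say nothing about absence.

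Single arrays set against the untreated array of the same genotype give the time course without a test. Mdm2 read 4.32, 5.13, 4.74 and 4.51 at 0, 4, 8 and 24 h in Atm+/+ and 4.18, 4.25, 4.51 and 4.55 in Atm-/-. Ccng1 read 4.72, 5.19, 5.10 and 4.91 in Atm+/+ and 4.74, 4.81, 4.80 and 5.24 in Atm-/-. Median log2 ratios of p53 targets at 4, 8 and 24 h were 0.30, 0.14 and 0.18 in Atm+/+ and 0.08, 0.13 and 0.13 in Atm-/-. NF-kB genes had 1.22, 1.77 and 0.67 in Atm+/+ and 0.78, 1.31 and 0.38 in Atm-/-. Interferon-stimulated genes had 0.06, 0.40 and 0.96 in Atm+/+ and 0.10, 0.58 and 0.95 in Atm-/-. S phase genes had -0.24, -0.53 and -0.97 in Atm+/+ and 0.05, -0.14 and -0.72 in Atm-/-. The 24 h values of Atm+/+ depend on the scale: in the first version they were -0.60 for S phase, 0.55 for p53 targets, 1.04 for NF-kB and 1.33 for interferon-stimulated genes, beside -0.70, 0.15, 0.40 and 0.97 in Atm-/-. The order of the genotypes for S phase genes at 24 h thus turned. AK036493 was among the largest rises in Atm+/+ at 4 h (4.64), Hyal1 the largest fall (-5.58), and Ccl3 stood at 5.36 in Atm-/- at 8 h. Hyal1 was also lower on the untreated Atm-/- array than on the untreated Atm+/+ array (-4.20). Its fall rests on that 1 untreated Atm+/+ array and cannot be read as a response to NCS. Ratios of at least 2-fold were higher for 156, 291 and 364 and lower for 64, 197 and 416 probes in Atm+/+. They were higher for 143, 164 and 429 and lower for 97, 181 and 540 in Atm-/-. Of these, 53, 94 and 94 higher and 7, 35 and 61 lower probes were shared between genotypes at 4, 8 and 24 h among probes measured in both. Chance would give 0.82, 1.97 and 6.57 higher and 0.24, 1.34 and 9.90 lower ones. The 24 h counts of Atm+/+ depend on the scale too, and the first version gave more 2-fold probes there, as given below.

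Between genotypes at 0, 4, 8 and 24 h the ratios of at least 2-fold numbered 395, 442, 391 and 763 higher and 447, 449, 578 and 706 lower in Atm-/-. S100a9, a neutrophil and macrophage calcium-binding gene, read -0.90, -0.64, -0.20 and -1.47 at 0, 4, 8 and 24 h in Atm+/+ and -4.42, -4.04, -3.72 and -4.47 in Atm-/-. The surface glycoprotein gene Cd200 had ratios of 3.55, 3.76 and 3.64 at 0, 4 and 8 h and an outlier spot on the Atm+/+ 24 h array. These counts have no replicates behind them and a single bad spot can enter them. Those at 24 h also depend on the scale of the Atm+/+ array, which the first version raised by 0.37 log2.

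**Figure D3:**
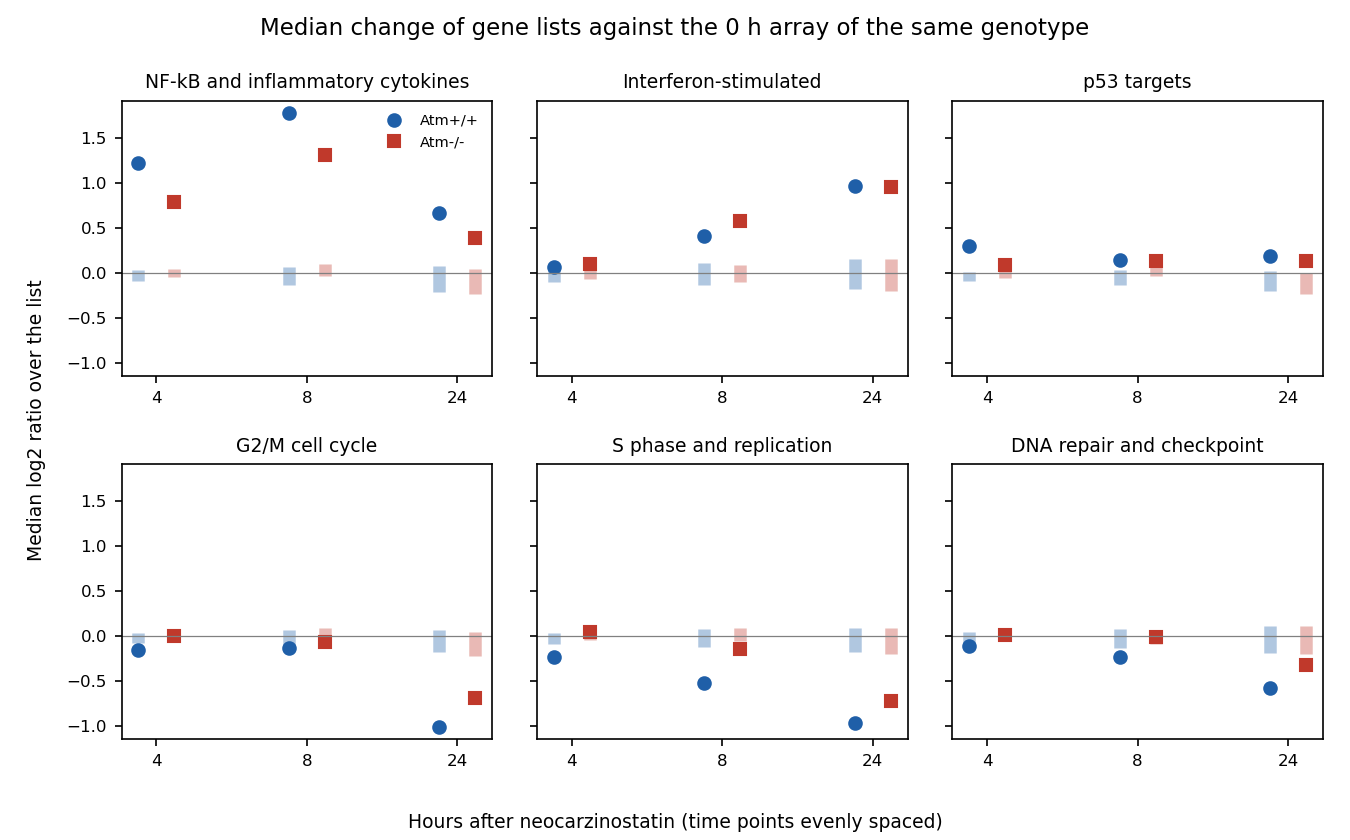
Median log2 ratio (vertical, same scale in every panel) at 4, 8 and 24 h after NCS with time points evenly spaced (horizontal). The panels show the NF-kB, interferon-stimulated, p53 target, G2/M, S phase and DNA repair lists. Points mark the list median of 1 array against the untreated array of the same genotype. Shaded bars mark 10000 random lists without the outer 2.5% on each side. G2/M genes reached -1.01 in Atm+/+ and -0.70 in Atm-/- at 24 h, and -0.64 and -0.67 with outlier spots removed before scaling.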

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

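The test of p53 targets was chosen after the result was seen, and the test of other probes of the same genes before.

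The Atm+/+ 24 h array held 1545 outlier spots against 54, 44 and 195 on the other Atm+/+ arrays. Its gap to the next array was 0.899 of the range (Dixon ratio for 4 arrays). Uneven pixels marked 1517 of them, and 72.2% were among the top quartile of spots by brightness. Of 14 such groups of 4 arrays 1 was beyond the critical value, and chance puts about 1 group in 20 there. The cause was not tested.

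Nfyb read -4.67 in Atm-/- at 24 h against -4.40 to -4.43 before (Dixon ratio 0.883), and AK012915 read -5.10 in Atm+/+ at 24 h against -4.41 to -4.49 (ratio 0.886). These were 2 of 28 groups of named genes, and chance puts about 1 in 20 beyond the critical value.

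Single probes stood far from the other arrays: 41 of 19198 read at least 2 log2 away on 1 array while the other 7 lay within 1 log2. Faults of single spots may lie behind them, since 0% of the 5 other probes of these genes moved at least 1 log2 the same way. But 4 genes are too few to tell (exact 95% interval up to 52.2%).

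Between genotypes the response to NCS differed by camera for S phase (adjusted p = 8.84e-08), DNA repair (0.00117), NF-kB (0.00117) and G2/M genes (0.0113), each with adjusted p = 0.717 with an estimated correlation and fry adjusted p from 0.496 to 0.762. Each response rests on 1 untreated array, so these may be deviations of that array. A weaker rise of p53 targets without Atm would lower their response (median difference -0.13). Its set test had adjusted p = 0.717 with an estimated correlation, so this stays open. Of 29 lists and control probes 0 moved in opposite directions in both genotypes at every time point.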

How the results depend on the processing

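Scaling to the array median, normexp on median spot intensities, outlier spots kept, and the percentile taken after removal of outlier spots were chosen after seeing the data. Of 12877 values of named genes under the alternatives 445 turned sign, 0 of them past the threshold with limma. Calls were less stable than signs. Of 175 printed gene values, 78 lost their call without a filter on detection. With the percentile taken after removal of outlier spots 51 did. Leaving out 1 array in turn lost more calls of these genes than it kept. Causes of the moves below were not tested. The labels give no replicate numbers, so the only pairing was that of the genotype arrays by time point, a term of their model. Slide and scan as a block was not run, since it could not be fitted for genotype, and normexp on mean spot signals was not run, since the files hold none. Signal over background limits what can be seen: genes near background give bounds, not folds.

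Leaving out 1 array in turn gave 1090 to 4220 calls for genotype (3418 with all), 0 to 41 for the response in both genotypes (48), 0 to 10 at 4 h (24), 0 to 85 at 8 h (60), 0 to 6 at 24 h (511), 0 to 3 in Atm+/+ (2), 0 to 6 in Atm-/- (6) and 0 for the difference of response.

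Leaving out time points gave 1140, 1090 and 1323 genotype calls without 0, 4 and 8 h, and for the response in both genotypes 19 without 4 h and 0 without 8 h (limma, 2892 at unadjusted p under 0.05). With time point left out, genotype had 2240 calls. With treatment in place of time point it had 2184, and the response in both genotypes 0 (1291 unadjusted).

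With the percentile taken after removal of outlier spots, the first version, genotype had 2250 calls, 24 h 33, Atm+/+ 1, and the single-array ratios of Atm+/+ at 24 h 1246 probes. Scaling to the array median gave 179 at 24 h and 1 in Atm+/+, and 9 in Atm-/- (44.4% higher in place of 33.3%). normexp gave 14 calls in Atm-/- and, for genotype, 3364 with 39.1% higher in place of 49.7%. Outlier spots kept gave 7 in Atm+/+ and 14 in Atm-/-.

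Without a filter on detection the calls were 2130 for genotype, 22 for the response in both genotypes, 9 at 4 h, 24 at 8 h, 0 at 24 h (limma, 6046 unadjusted), 105 in Atm+/+ and 259 in Atm-/-. With probes well above background on all 8 arrays they were 15, 38 and 1146 at 4, 8 and 24 h. eBayes with trend and robust gave 100 in both genotypes, 50, 112 and 1651 at 4, 8 and 24 h and 1 in Atm+/+. The authors' values, noncoding only, gave 593 for genotype, 4 for the response in both genotypes and 1, 4 and 1 at 4, 8 and 24 h. The arrays of a genotype alone gave 0 calls in Atm+/+ (limma, 703 unadjusted) and 3 in Atm-/-, 0 of them shared.

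Single-array ratios are counts of probes at 4, 8 and 24 h in Atm+/+, the same in Atm-/-, and then Atm-/- against Atm+/+ at 0, 4, 8 and 24 h. At least 3-fold: 80, 125, 104; 78, 96, 144; and 166, 196, 212, 327. The authors' values: 63, 134, 167, then 73, 121, 377, then 255, 253, 255, 431. Well above background on at least 1 of both arrays: 414, 859, 1183, then 467, 738, 1527, then 1389, 1411, 1556, 2243. normexp: 113, 253, 479, then 118, 181, 513, and 438, 469 and 536 at 0, 4 and 8 h.

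With an estimated correlation camera called 0 lists in each of the 8 comparisons, against 10 for genotype, 8 for the response in both genotypes, 4, 6 and 10 at 4, 8 and 24 h, 7 in Atm+/+, 5 in Atm-/- and 4 for the difference of response, and 5, 2, 2, 2, 2, 2, 0 and 1 lists had unadjusted p under 0.05. In the same order fry called 10, 4, 1, 2, 10, 0, 0 and 0 lists. The direction of some lists that did not pass turned. With quantile normalization these were extracellular matrix for the response in both genotypes (adjusted p = 0.476), in Atm+/+ (0.704) and in Atm-/- (0.839), endothelial markers at 8 h (0.967) and imprinted genes at 24 h (0.903). With the mean of all probes of a gene they were endothelial markers at 8 h (0.989) and imprinted genes at 24 h (0.794).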

Other observations

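The tests of cell share, macrophages, culture time, sex chromosomes, slide and splits were chosen after the result was seen, and the test of chromosome 9 before.

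Noncoding classes were compared as shares of probes called. Between genotypes limma called 16.6% of 589 intergenic, 13.9% of 929 antisense, 13.6% of 3264 sense-overlapping, 95 of 790 bidirectional and 13.7% of 991 other transcripts and 9.20% of 174 without a class, against 15.1% of 16533 other probes. At 24 h after NCS it called 1.19%, 1.19%, 1.88%, 1.90%, 1.63% and 0.575% of them, against 2.43% of other probes. Differences among classes were not tested.

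AK007219 read -2.58, -3.96, -4.71 and -5.99 at 0, 4, 8 and 24 h in Atm-/- and -0.38 to 0.20 in Atm+/+.

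Of 34 inflammatory genes 10 rose after NCS with the genotypes pooled, and limma called 0 within Atm+/+ or Atm-/- (0 adjusted over the list alone). The camera call of the list was lost with an estimated correlation (adjusted p = 0.245 pooled, 0.398 and 0.666 within). A larger share of blood cells or macrophages would have raised their markers alike. At 4 h the 14 markers had a median change of 0.0278 (SD 0.47, range -0.61 to 1.38) against 4.75 for the 5 called inflammatory genes and 1.15 for their whole list, which argues against it as the whole cause at 4 h. The markers had medians of 0.33 at 8 h and 0.55 at 24 h, beside 1.70 and 0.87 for the inflammatory list, so a larger share stays open for later time points. Activation of macrophages already in the dishes stays open. On both 0 h arrays 12 of the 14 markers were well above background (Lyz2 at 3.22 in Atm+/+ and 2.03 in Atm-/-). But so were 21408 of the 23296 kept probes, so this count does not show that macrophages were present. Fibroblasts also make some of the markers, such as Cd14, and these lists cannot tell fibroblasts from macrophages. Time in culture or handling stays open too, with 0 untreated arrays at 4, 8 or 24 h. So does the DNA damage itself.

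Probes that differed between genotypes were spread over the chromosomes. Genes of X and Y made up 4.53% of the called probes with a known chromosome (112 of 2474, with 944 more called probes unplaced). This argues against sex-linked genes as the whole direct cause, while other effects of embryo sex stay open. Of the tested probes, 17.9% of 602 on X and 80% of 5 on Y were called, against 15.0% of those placed elsewhere. On chromosome 9, 16.4% of 890 probes were called against 14.9% on other autosomes (Fisher exact two-sided p = 0.227). This missed the mark set beforehand for DNA that came with the targeted allele, 2 times the share of other autosomes. The 146 called probes there, of the 2474, argue against such DNA as the whole direct cause. A share over the whole chromosome cannot show a segment around Atm, so a part in the difference stays open. Slide and scan cannot be told apart from genotype, with 0 slides that hold both. Loss of Atm, and the lower blood and macrophage markers of Atm-/- (median -1.13), stay open as well.

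With time point left out, 1 of 35 splits of the 8 arrays, the real one, gave as many calls as the genotypes (2240, highest other 3). With time point in the model 1 of 8 splits did (3418, highest other 1), too few splits for a share under 0.05. Every other split puts arrays of both genotypes, and so of both slides, on each side, which leaves it few calls. The splits thus show that arrays of a genotype were alike and cannot exclude chance. They also treat the arrays as independent, so they say nothing about chance differences between embryos, cultures or slides.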
